A study of Homo sapiens with 7 samples.

How the data were processed

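RNA from untreated human B cells was measured on Affymetrix expression arrays, with 1 array per sample. Per the labels, 5 samples were leukemic cells from chronic lymphocytic leukemia (CLL) and 2 were normal B cells, all as total RNA isolated on columns and labelled with biotin. The series' design text speaks of 5 samples in total, while 7 are listed, and all 7 were used. The labels do not say that the samples came from separate donors, so p-values measure only the spread between these samples, which may be technical. No sort, purity or batch is given in the sources used here.

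The deposited values are intensities on a linear scale, 1 per probe set and array, made by the authors with MAS5, per the submitters' processing notes. The MAS5 version and any filter are not given in the sources used here. The values themselves show that each array had been scaled to a common level: after removal of the top and bottom 2% of probe sets, the mean intensity lay between 2500.7 and 2500.9 on all 7 arrays. Such scaling makes arrays comparable only if total signal is alike, and MAS5 values of dim probe sets vary more than those of bright ones. No detection calls or background estimates were used here, so no value is given as a bound. For arrays, the number of arrays limits the precision of each difference, here 5 against 2. No genome build was used and no coordinates are printed.

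Of 22283 probe sets on the array, 68 were controls and were left out of the tests. The platform annotation paired 19071 probe sets with 1 gene symbol and 1043 with several, and 2169 were not listed with a gene. Symbols were looked up through gene identifiers in a table of human genes, which changed 0 of them. Genes were named only from probe sets with 1 symbol, and list members paired with no such probe set were not analysed here. A probe set was tested if it was brighter than its array's own median on at least 2 of the 7 arrays, which left 12819 probe sets of 7655 genes. For 2466 genes more than 1 probe set was tested. The probe set with the highest mean log2 intensity then stood for the gene, and probe sets that pointed the other way are mentioned where the gene is named.

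Differences are log2 intensity in CLL cells minus normal B cells, with no pseudocount, tested two-sided with limma (version 3.58.1, R version 4.3.3) using lmFit and eBayes with an intensity trend over all 7 arrays. Errors written after ± are standard errors (SE) of that fit unless given as SD. Values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with 0.05 as the threshold. The fit had 5 residual and 4.26 prior degrees of freedom. Gene lists were tested with camera from limma on 1 probe set per gene, with a preset correlation of 0.01 between genes, and adjusted over 27 gene lists and, separately, over 9 lists of cell type markers. Each list needed at least 5 tested members, or 3 for cell types. Camera with a correlation estimated for each list was run beside it. Within each list, the members' own p-values were also adjusted over the list alone. The mean of each list was set against all 21 ways of splitting the 7 samples into 2 and 5, an exact two-sided permutation test whose smallest possible p is 0.0476.

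The tests, filter, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule took up to 12 genes per direction past the threshold over all probe sets with no overlap between the groups, the 3 members with the smallest p-value from each list, and ZAP70, CD38 and LPL. Its first part yielded 0 genes, so genes with an adjusted p under 0.12 were singled out after their values were seen and are given as such. Sex-linked transcripts and individual immunoglobulin, T cell receptor and HLA-DRB or HLA-DQ genes were left out of the named genes.

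The scripts were tested on simulated data built on these 12819 probe sets over 10 runs. Of 500 probe sets changed by each size, 2.8% were called at a 2-fold change, 32.2% at 4-fold, 61% at 8-fold and 66.6% at 16-fold, and 39 unchanged probe sets were called in all runs together. A list of 14 genes shifted by 1 on the log2 scale had an unadjusted camera p under 0.05 in 10 of 10 runs. Of 500 lists of unchanged genes, 12 (2.4%) had such a p. Simulated genes were uncorrelated, while the estimated correlation of the 7 called gene lists lay between 0.225 and 0.749. These rates therefore do not carry over to those lists. Alternatives tried were quantile normalization, centring on the median, a pseudocount, no filter and a stricter filter, variance models without the trend or with robust estimation, array weights, 1 value per gene, a 2-fold minimum, a replicate block and leaving out each sample in turn. A fit without CLL samples 3 and 4 was added after the data had been seen.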

Results

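Gene expression was profiled in 7 samples of untreated B cells: 2 of normal B cells and 5 of cells from chronic lymphocytic leukemia, a malignancy of mature B cells. The comparison asks how the transcript levels of the leukemic cells differ from those of normal B cells. Median intensity per array, a measure of overall brightness, lay between 780.3 (CLL sample 3) and 1260 (CLL sample 1), with 838.7 and 951.7 in the normal samples. The ratio of the 3' to the 5' probe set of GAPDH, a measure of RNA integrity, was 2.03 in CLL sample 3, 1.38 in normal sample 1 and at most 1.15 in the other samples. The corresponding ratio for ACTB was 3.16 in normal sample 1 and 2.08 in CLL sample 3, against 1.06 to 1.40 elsewhere.

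The CLL samples differed from each other about as much as they differed from normal B cells. Over the 12819 tested probe sets, the correlation of log2 intensity between CLL samples had a median of 0.804 (range 0.706 to 0.865, 10 pairs), and that between normal and CLL samples 0.808 (range 0.786 to 0.840, 10 pairs). The 2 normal samples correlated at 0.917. These correlations are across genes, which are not independent replicates. The median SD of a probe set was 0.52 log2 units among CLL samples (n = 5) and 0.25 among normal samples (n = 2).

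SIT1, SYNE2, TESC, ROR1 and GZMK were brighter in all 5 CLL samples than in both normal samples, and BCL2A1 was dimmer in all 5. These genes and RASGRF1, 7 in all, had an adjusted p under 0.12 and were chosen after their values were seen, and none passed the threshold over all probe sets. SIT1, an adaptor that tunes antigen receptor signalling, differed by 2.52 ± 0.31 on the log2 scale (5.74-fold, adjusted p = 0.0926), and SYNE2, which links the nucleus to the cytoskeleton, by 2.37 ± 0.31 (5.18-fold, adjusted p = 0.102). The calcium-binding protein gene TESC differed by 2.40 ± 0.35 (5.29-fold, adjusted p = 0.115). The orphan receptor gene ROR1 differed by 3.08 ± 0.44 (8.48-fold) and the cytotoxic granule protease gene GZMK by 4.23 ± 0.58 (18.8-fold), both with an adjusted p of 0.114. BCL2A1, a pro-survival gene induced by NF-kB, stood at −2.15 ± 0.31 in CLL cells relative to normal B cells (adjusted p = 0.114). RASGRF1, an exchange factor for RAS proteins, had 1 probe set at 6.69 ± 0.76 (adjusted p = 0.0926), higher in all 5 CLL samples, while its brighter probe set gave 0.98 ± 0.51 (adjusted p = 0.814) and was higher in 4 of 5. The size of the first is uncertain, since its mean in normal B cells was 5.71 on the log2 scale, below the lower quartile of 8.15 of those arrays, and GZMK at 7.56 lay below it too.

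Across all probe sets, limma called 0 higher and 0 lower in CLL cells at an adjusted p under 0.05, and the smallest adjusted p was 0.0926. At an unadjusted p under 0.05 there were 828 probe sets, 396 higher and 432 lower, where chance alone gives 640.95. Without normal sample 1 these counts were 174 and 215, and without normal sample 2 they were 245 and 177. Centring each array on its median gave 232 higher and 444 lower. Other settings raised these counts: array weights gave 800 and 875, and the replicate block 803 and 956. No filter gave 603 and 654, but with 22215 probe sets tested instead of 12819. At an adjusted p under 0.05, a pseudocount called 2 higher and 6 lower, a fit without the intensity trend 1 and 7, and array weights 14 and 20. The groups did not overlap for 1568 probe sets, or 12.2% of those tested, against 9.52% by chance. Of these, 239 were at least 2-fold higher and 305 at least 2-fold lower in CLL cells. Of 27 gene lists, 7 passed the threshold (1 higher, 6 lower), and 0 did with an estimated correlation. Of 9 cell type lists, 6 passed (2 higher, 4 lower), and 1 did with an estimated correlation. When 1 sample was left out, the mean moved by more than 1.5 times or changed sign in 17 of the 20 gene lists that were not called and in 0 of the 7 that were, and in 3 of 3 and 4 of 6 cell type lists. Many uncalled lists had means near 0, where a small shift passes that limit. The contrast therefore does not show that called lists are more stable.

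**Figure D1:**
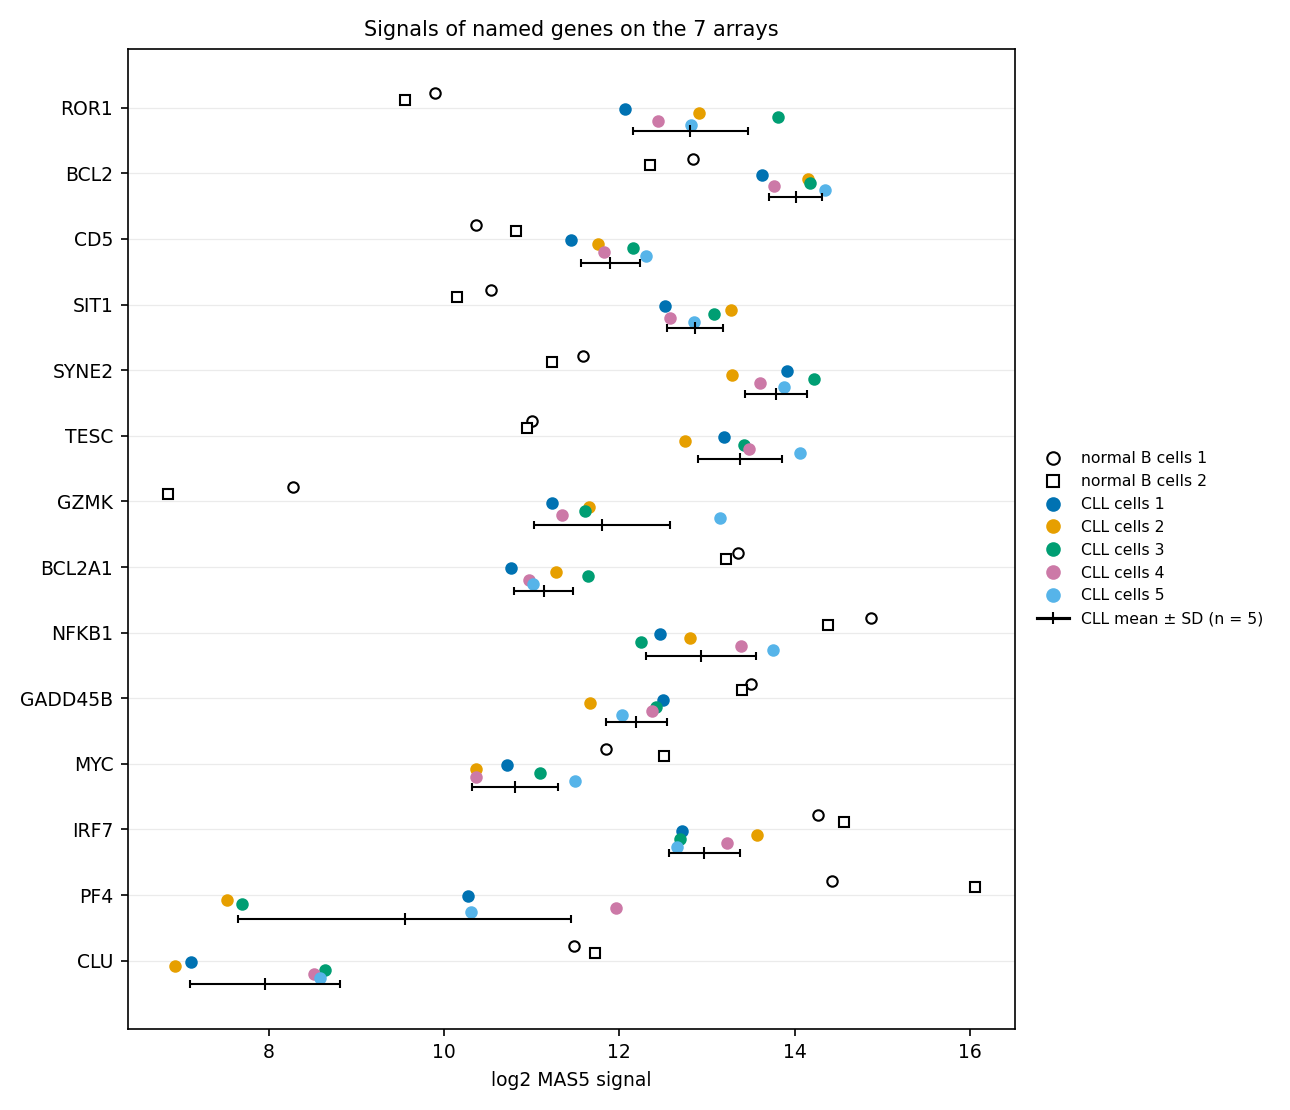
Log2 MAS5 intensity of 14 genes in each sample, with open symbols for the 2 normal B cell samples, filled symbols for the 5 CLL samples and a bar for the CLL mean ± SD (n = 5). ROR1, BCL2, CD5, SIT1, SYNE2, TESC and GZMK lie higher in all 5 CLL samples than in both normal samples, and BCL2A1, NFKB1, GADD45B, MYC, IRF7, PF4 and CLU lie lower in all 5.

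Genes known to be high in CLL were higher in these CLL cells as a group. Of the 10 tested members, 8 had a difference above 0 and 4 passed the threshold when adjusted over the list alone, against 0 over all probe sets. ROR1 was among these 4, with BCL2, which blocks mitochondrial apoptosis (1.42 ± 0.29, 2.68-fold), and CD5, a surface receptor shared by T cells and CLL cells (1.30 ± 0.32, 2.47-fold). The remaining gene, FMOD, which encodes the matrix proteoglycan fibromodulin, was named after its value was seen and differed by 3.25 ± 1.16. FCER2, the low-affinity IgE receptor CD23, differed by 1.26 ± 0.85 and was higher in 4 of 5 CLL samples, lower in the other. In 1 of these 4, CLL sample 4, it all but tied with normal sample 2 (10.8417 against 10.8416 on the log2 scale). The list mean was 1.37 and its median 1.36 (camera, adjusted p = 0.000493, and adjusted p = 0.636 with an estimated correlation). The mean of the list was −0.27 in CLL sample 1 relative to normal B cells and between 0.84 and 2.28 in the other 4, and the exact permutation p over 21 splits was 0.286. For BCL2, 1 of 4 tested probe sets pointed the other way (−1.03). Markers of T cells, which also express CD5, were higher in the same comparison, with a list mean of 0.64 and 8 of 9 genes above 0 (CD6 at 1.23 ± 0.61 and CD2 at 1.06 ± 0.56).

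NF-kB target genes, immediate early genes and interferon response genes were lower in CLL cells. All 14 tested NF-kB targets lay below 0, with a mean of −1.02 (adjusted p = 3.81e-06, and adjusted p = 0.636 with an estimated correlation). BCL2A1 and NFKB1, which encodes a subunit of NF-kB itself (−1.69 ± 0.42), passed when adjusted over the list alone, and the activation marker CD83 stood at −1.53 ± 0.52. By sample, the NF-kB mean relative to normal B cells lay between −1.21 and −1.92 in CLL samples 1, 2 and 3, and was −0.23 in both CLL samples 4 and 5. Those 2 samples also had the highest means of erythroid markers (6.88 and 3.95). Of 21 immediate early genes, which respond within minutes to cell stimulation, 20 lay below 0, with a mean of −0.99 (adjusted p = 5.50e-07, and adjusted p = 0.636 with an estimated correlation). GADD45B, a stress response gene (−1.25 ± 0.30), was the 1 gene past the threshold adjusted over the list alone, and 1 of its 4 tested probe sets pointed the other way (0.68). MYC, a driver of cell growth (−1.37 ± 0.39), and the transcription factor gene EGR3 (−2.60 ± 0.79) were also lower in all 5 CLL samples than in both normal samples.

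Of 22 interferon response genes, 19 lay below 0, with a mean of −1.06 (adjusted p = 4.93e-05, and adjusted p = 0.750 with an estimated correlation). IRF7, which controls type I interferon genes, stood at −1.45 ± 0.32 and was the 1 gene past the threshold adjusted over the list alone. RSAD2, an antiviral enzyme (−3.47 ± 1.01), was lower in 4 of 5 CLL samples, and IFI44 (−2.09 ± 0.67) in 5 of 5. The interferon list was not shifted in every CLL sample: its mean relative to normal B cells was 0.08 in CLL sample 4 and between −0.30 and −1.98 in the other 4. CLL sample 4 also had the highest means of monocyte (1.47), T cell (1.99), cytotoxic cell (2.45) and erythroid markers (6.88). The next highest interferon and monocyte means of the CLL samples were both in CLL sample 2 (−0.30 and −0.31). Any link between them was not tested. In the same comparison, markers of platelets, neutrophils, plasma cells and monocytes were lower in CLL cells, with list means of −3.67, −2.05, −1.15 and −0.55, and the normal sample with the ACTB ratio of 3.16 was 1 of the 2 that set the baseline. Over the members of these 3 lists, 0 passed the threshold over all probe sets, and the exact permutation p of the mean was 0.143 for NF-kB targets, 0.0952 for immediate early genes and 0.238 for interferon response genes.

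Genes of glycolysis, the proteasome and the ribosome were lower in CLL cells by smaller amounts. Among 19 glycolysis genes, 15 lay below 0, with a mean of −0.46 (adjusted p = 0.000493, and adjusted p = 0.636 with an estimated correlation), with LDHA at −0.90 ± 0.26, ENO1 at −0.88 ± 0.27 and GAPDH at −0.67 ± 0.21. By sample, the glycolysis mean lay between −0.69 and −0.83 in CLL samples 1, 2 and 3, and was 0.01 and −0.05 in samples 4 and 5, the samples with the highest means of erythroid markers (6.88 and 3.95). Among 24 proteasome genes, 20 lay below 0, with a mean of −0.31 (adjusted p = 0.000384, and adjusted p = 0.636 with an estimated correlation). The core subunit genes PSMA2, PSMA7 and PSMA3 stood at −0.70 ± 0.24, −0.71 ± 0.25 and −0.65 ± 0.24. The proteasome mean was −0.03 in CLL sample 2, within the range of the normal samples (0.09 and −0.09), and between −0.36 and −0.39 in the other 4. All 21 ribosomal protein genes lay below 0, with a mean of −0.40 (adjusted p = 4.93e-05, and adjusted p = 0.816 with an estimated correlation), among them RPL32 at −0.53 ± 0.24 and RPS19 at −0.64 ± 0.34. The ribosomal mean was 0.07 in CLL sample 1, within the range of the normal samples (0.10 and −0.10), and between −0.24 and −0.85 in the other 4. In these 3 lists, 0 genes passed adjusted over the list alone and 0 over all probe sets, and the exact permutation p of the mean was 0.238 for glycolysis, 0.0952 for the proteasome and 0.190 for the ribosome. Quantile normalization ended the ribosomal call, with a mean of −0.14 and an adjusted p of 0.416.

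**Figure D2:**
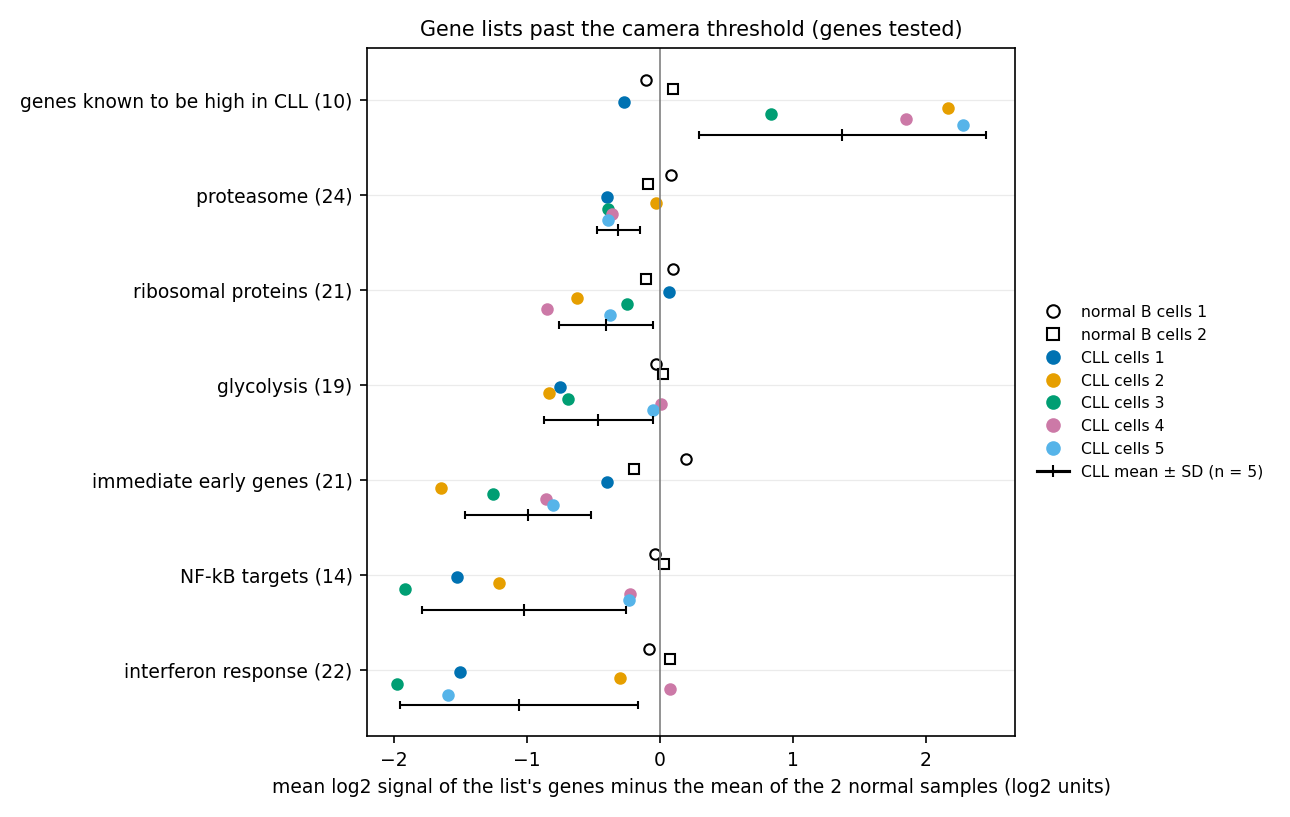
Mean log2 intensity of the tested genes of each of the 7 called gene lists in each sample, relative to the mean of the 2 normal samples, with open symbols for normal B cells, filled symbols for CLL cells and a bar for the CLL mean ± SD (n = 5). Immediate early genes lie below both normal samples in all 5 CLL samples, and the mean of genes known to be high in CLL is −0.27 in CLL sample 1 against 0.84 to 2.28 in the other 4.

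Lists of apoptosis genes were not called, although some members stood apart. The pro-survival BCL2 family (5 genes, mean −0.05, median 0.21, camera direction below 0, adjusted p = 0.974) held BCL2A1 and BCL2, which both passed adjusted over the list alone and lay in opposite directions. Among 8 pro-apoptotic genes of the family (mean 0.27, adjusted p = 0.614), BAX, a pore former of the mitochondrial membrane, stood at 0.89 ± 0.38, HRK at 2.30 ± 0.99 and BID at −0.75 ± 0.33. Among 10 death receptor and inhibitor of apoptosis genes (mean −0.11, median −0.22, camera direction above 0, adjusted p = 0.930), the initiator caspase gene CASP8 stood at 1.16 ± 0.35. The 16 p53 and DNA damage genes had a mean of 0.02 (adjusted p = 0.614), with the repair gene DDB2 at 0.69 ± 0.33.

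Lists of B cell receptor signalling and B cell identity were not called either. The receptor signalling list (24 genes) had a mean of 0.10 (adjusted p = 0.666), with the kinase gene BLK at 1.04 ± 0.29, the exchange factor gene VAV2 at 1.65 ± 0.53 and MALT1, a signalling protease, at −0.94 ± 0.36. VAV2 stood at 0.81 without normal sample 1 and 2.49 without normal sample 2, and MALT1 at −0.57 without normal sample 1. Surface genes known to be dim in CLL (8 genes) had a mean of −0.02, a median of 0.08 and a camera direction above 0 (adjusted p = 0.928), with CD81 at 0.36 ± 0.41 (0.14 without CLL sample 3). The 13 pan B cell markers had a mean of −0.05, a median of 0.11 and a camera direction above 0 (adjusted p = 0.783), with the receptor chain gene CD79A at −0.84 ± 0.47. B cell differentiation factors (16 genes) had a mean of −0.22 (adjusted p = 0.614), with ID2, an inhibitor of transcription factors, at −2.05 ± 0.68 (−1.15 without normal sample 2). The 11 genes of MHC class II presentation had a mean of −0.34 (adjusted p = 0.0879), with the chaperone gene CD74 at −0.79 ± 0.47 (−0.44 without CLL sample 1). Their mean was −1.19 in CLL sample 1, and −0.12 in the comparison without that sample (adjusted p = 0.534), while the list was called without CLL sample 2 (adjusted p = 0.0452), CLL sample 3 (adjusted p = 0.0439) or both CLL samples 3 and 4 (mean −0.47, adjusted p = 0.0276). With an estimated correlation the adjusted p of the MHC class II list was 0.894. Memory B cell genes (8 genes, mean 0.16) and naive B cell genes (7 genes, mean −0.15) both had an adjusted p of 0.614. CD27, a memory B cell marker of the TNF receptor family, stood at 1.77 ± 0.39 and passed adjusted over the list alone, and the costimulatory gene CD86 stood at −1.51 ± 0.49.

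Further signalling lists were not called. The 13 TNF receptors and ligands had a mean of −0.14 (adjusted p = 0.928), with TNF at −1.27 ± 0.53 and TNFRSF9 at −1.70 ± 0.66 (−0.88 without normal sample 2), and CD27 again past the threshold adjusted over the list alone. Wnt signalling (12 genes, mean 0.21, adjusted p = 0.928) held ROR1 and AXIN1, a scaffold of beta-catenin breakdown (1.78 ± 0.40), both past the threshold adjusted over the list alone, and WNT5A, a ligand of ROR1, at −2.69 ± 1.01, of uncertain size since its mean in CLL cells was 7.71, below the lower quartile of 8.01. The exact permutation p of the Wnt mean was 0.0476, and 0.643 after adjustment over the 27 gene lists. Chemokine receptors and homing genes (15 genes) had a mean of −0.10 (adjusted p = 0.930), with the adhesion gene PECAM1 at 1.14 ± 0.49.

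Lists of the cell cycle, nucleoside metabolism, chaperones, oxidative phosphorylation and chromatin were not called. The 15 proliferation genes had a mean of −0.26 (adjusted p = 0.451) and 0 of them had an unadjusted p under 0.05, with TYMS, an enzyme of nucleotide synthesis, at −1.13 ± 0.59. Their mean was −0.08 without normal sample 1 and −0.43 without normal sample 2. The 10 G1 cyclins and inhibitors had a mean of 0.29 (adjusted p = 0.704), with cyclin D1 (CCND1) at 3.53 ± 1.46 and the inhibitor gene CDKN1A at −1.68 ± 0.70. The CCND1 mean in normal B cells was 7.07 on the log2 scale, below the lower quartile of 8.15 of those arrays, so its size is uncertain. Nucleoside metabolism (14 genes) had a mean of −0.57 (adjusted p = 0.0538), with adenosine deaminase (ADA) at −1.56 ± 0.57 and the ectonucleotidase gene NT5E at −3.15 ± 1.32, of uncertain size since its mean in CLL cells was 7.24, below the lower quartile of 8.01 of those arrays. This list was called with quantile normalization (adjusted p = 0.0449), median centring (0.0305) or a pseudocount (0.0344), and without CLL sample 2 (0.0207), 3 (0.0439) or 4 (0.0380). With a stricter filter its mean was −0.24 (adjusted p = 0.638), and with an estimated correlation its adjusted p was 0.636. Its exact permutation p was 0.0476, the smallest possible, and 0.643 after adjustment over the 27 gene lists. Heat shock proteins and chaperones (17 genes) had a mean of −0.28 (adjusted p = 0.0878), with DNAJA1 at −0.88 ± 0.39, and were called without CLL sample 2 (mean −0.40, adjusted p = 0.00304) or CLL sample 5 (mean −0.35, adjusted p = 0.0320), while the mean was −0.15 without CLL sample 3. With an estimated correlation the adjusted p of the chaperone list was 0.894. Oxidative phosphorylation (25 genes, mean −0.10, adjusted p = 0.451) and chromatin modifiers (20 genes, mean 0.00, median 0.04, camera direction below 0, adjusted p = 0.928) had 0 members with an unadjusted p under 0.05.

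ZAP70, LPL and CD38, which are known to differ between cases of CLL, did not pass the threshold, and their spread was not tested. ZAP70, a T cell receptor kinase found in some cases of CLL, had an SD of 1.77 among CLL samples (n = 5) and differed from normal B cells by 1.05 ± 1.03 (adjusted p = 0.932). Its log2 intensity was 12.27 in CLL sample 4 and 12.60 in CLL sample 5, against 8.77 to 9.55 in the other 3. CLL sample 4 also had the highest means of T cell (1.99) and cytotoxic cell (2.45) markers relative to normal B cells. In CLL sample 5 these means were 0.50 and 0.41, against 0.48 and −0.01 in CLL sample 1, whose ZAP70 was 9.55. LPL, lipoprotein lipase, had an SD of 2.36 (n = 5) and a difference of 0.40 ± 1.33 (adjusted p = 0.984), and the ectoenzyme gene CD38 an SD of 1.64 (n = 5), against 1.70 between the normal samples (n = 2), and a difference of −1.50 ± 1.07 (adjusted p = 0.886). CD38 stood at −0.30 without normal sample 1, −2.70 without normal sample 2 and −0.85 without CLL sample 3. ZAP70 stood at 0.61 without CLL sample 4 and 0.53 without CLL sample 5, and LPL between −0.17 (without CLL sample 4) and 1.38 (without CLL sample 3). The 8 prognostic genes had a mean of −0.07, a median of 0.04 and a camera direction below 0 (adjusted p = 0.869).

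Platelet transcripts were far lower in CLL cells than in normal B cells. All 8 tested platelet markers lay below 0, with a mean of −3.67 and a median of −3.90 (adjusted p = 4.84e-11), and the call held with an estimated correlation (adjusted p = 0.0144). The chemokine gene PF4 stood at −5.69 ± 1.12, clusterin (CLU) at −3.65 ± 0.78 and the integrin gene ITGA2B at −1.93 ± 0.42, each lower in 5 of 5 CLL samples. The size for CLU is uncertain, since its mean in CLL cells was 7.96 on the log2 scale, below the lower quartile of 8.01 of those arrays. PF4, CLU and ITGA2B were 3 of the 6 markers past the threshold adjusted over the list alone, against 0 over all probe sets. The exact permutation p of the list mean was 0.0476, the smallest that 21 splits allow, and 0.429 after adjustment over the 9 cell type lists. Of the 8 markers, 8 had a mean above the typical array median in normal B cells and 2 in CLL cells. Genes bright only in the 2 normal samples would pass the filter, so the size of this difference may be overstated.

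Markers of other blood cells also differed between the groups. Of 7 neutrophil markers 6 lay below 0, with a mean of −2.05 (adjusted p = 0.000534, and adjusted p = 0.295 with an estimated correlation), among them the granule protein genes CAMP at −4.01 (95% interval −6.26 to −1.76) and LTF at −3.70 ± 1.61, and CAMP and S100P (−3.21 ± 1.05) passed adjusted over the list alone. Of 8 plasma cell markers 7 lay below 0, with a mean of −1.15 (adjusted p = 0.0196, and adjusted p = 0.295 with an estimated correlation), with SLAMF7 at −1.71 ± 0.70 and JCHAIN, the joining chain of secreted antibodies, at −2.76 ± 1.59 (−1.67 without normal sample 1 and −1.71 without CLL sample 3). Monocyte markers (13 genes) had a mean of −0.55 and a median of −0.88 (adjusted p = 0.0242, and adjusted p = 0.589 with an estimated correlation), but went both ways: cystatin C (CST3) at −1.98 ± 0.51, past the threshold adjusted over the list alone, and lysozyme (LYZ) at −1.93 ± 0.66, against the endotoxin co-receptor gene CD14 at 2.56 ± 0.97. The plasma cell call was lost without normal sample 1 (mean −0.60, adjusted p = 0.225) and without CLL sample 5 (adjusted p = 0.0612). The neutrophil call was lost without normal sample 2 (adjusted p = 0.0523). The monocyte call was lost without normal sample 2 (mean −0.24, adjusted p = 0.297), CLL sample 1 (0.0519), CLL sample 3 (mean −0.35, 0.0955) or CLL sample 5 (mean −0.26, 0.210), while the mean was −0.86 without normal sample 1 and −1.05 without CLL sample 4.

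Erythroid and T cell markers were higher in CLL cells. All 7 erythroid markers lay above 0, with a mean of 2.58 (adjusted p = 0.00765, and adjusted p = 0.548 with an estimated correlation), with haemoglobin beta (HBB) at 2.71 ± 0.99 and haemoglobin delta (HBD) at 3.25 ± 1.54, and 0 passed adjusted over the list alone. The erythroid mean relative to normal B cells was 6.88 in CLL sample 4 and 3.95 in CLL sample 5, against 0.39 to 1.02 in the other 3, and the 2 normal samples lay 0.97 above and 0.97 below their own mean. Without normal sample 2 the erythroid call was lost (mean 1.61, adjusted p = 0.176), and without CLL sample 4 the mean was 1.50 (adjusted p = 0.0423). HBB stood at 5.09 without normal sample 1 and at 0.34 without normal sample 2. Of 9 T cell markers 8 lay above 0, with a mean of 0.64 (adjusted p = 0.0303, and adjusted p = 0.589 with an estimated correlation), with CD6 at 1.23 ± 0.61 (0.71 without normal sample 1) and CD2 at 1.06 ± 0.56 (0.69 without CLL sample 4). The T cell mean was 1.99 in CLL sample 4 and between −0.05 and 0.50 in the other 4, and the call was lost without normal sample 1 (0.112), normal sample 2 (0.0523) or CLL sample 4 (mean 0.30, adjusted p = 0.163).

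Markers of natural killer and cytotoxic cells (11 genes, mean 0.61, adjusted p = 0.0781) were not called but held 3 genes past the threshold adjusted over the list alone. GZMK and GZMA (2.04 ± 0.57), which encode granule proteases, were higher in 5 of 5 CLL samples, and GZMB, another granule protease gene (−3.25 ± 1.04), was lower in 4 of 5. Without normal sample 2 GZMA stood at 1.33 and GZMB at −1.93. The list mean relative to normal B cells was 2.45 in CLL sample 4 and between −0.01 and 0.41 in the other 4. In the comparison without normal sample 1, with only normal sample 2 as baseline, the mean was 0.96. That was the highest mean among the 17 settings with the preset correlation. Among the settings that kept both normal samples, the list was called without CLL sample 2 (adjusted p = 0.0442) or 3 (0.0418) and with median centring (0.0280). With an estimated correlation its adjusted p was 0.589. The mean was 0.26 without normal sample 2 (adjusted p = 0.404) and 0.15 without CLL sample 4 (adjusted p = 0.829). Plasmacytoid dendritic cell markers (4 genes) had a mean of −0.43, a median of 0.12 and a camera direction below 0 (adjusted p = 0.583), with the cytokine receptor gene IL3RA at −2.77 ± 1.06. Their mean was −1.17 without normal sample 1 (adjusted p = 0.0835) and 0.30 without normal sample 2 (adjusted p = 0.472).

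**Figure D3:**
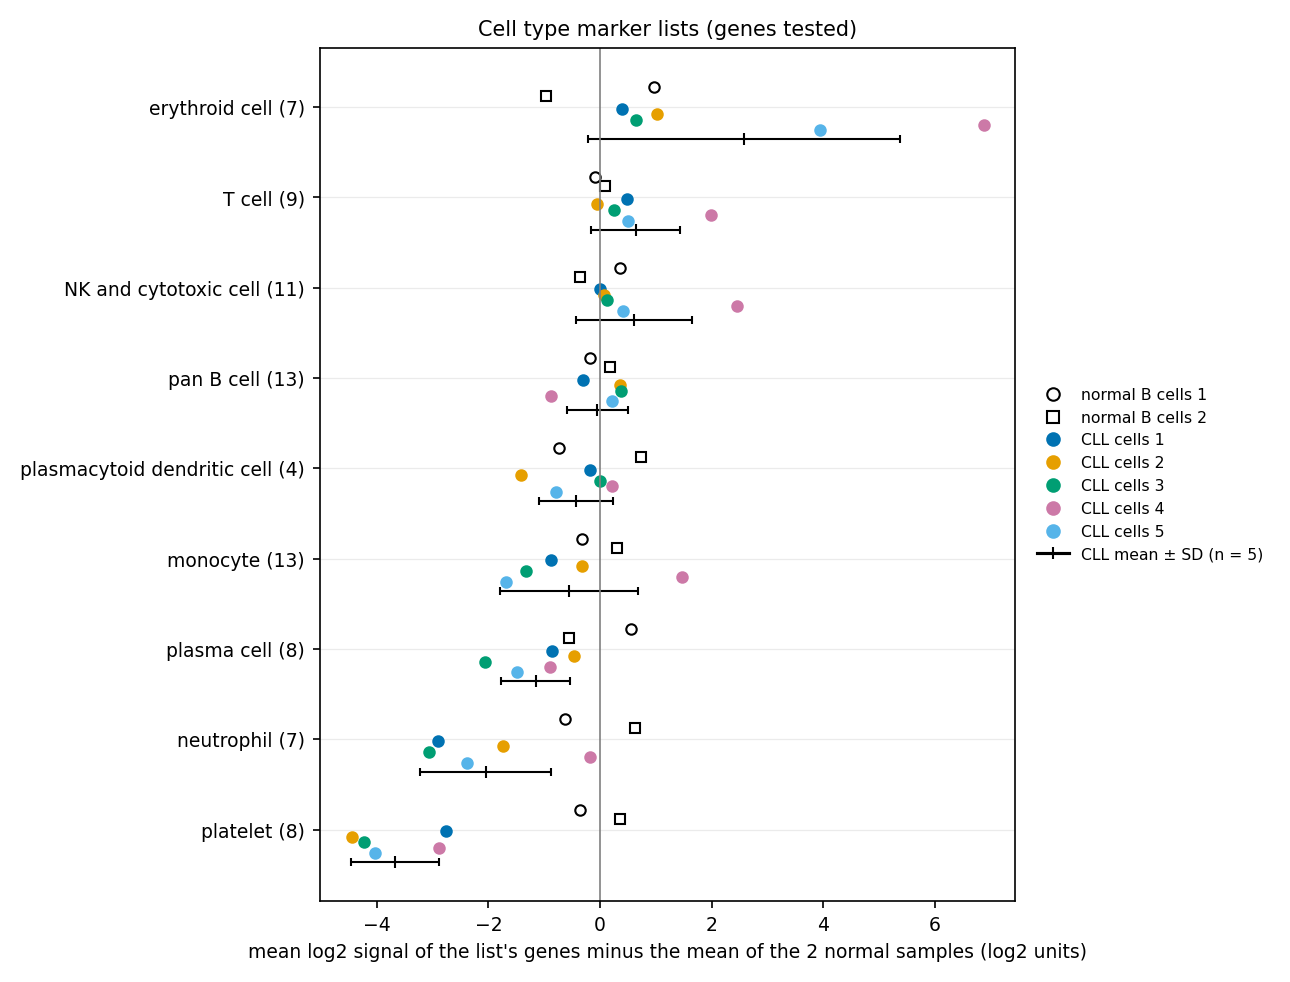
Mean log2 intensity of the tested markers of each cell type in each sample, relative to the mean of the 2 normal samples, with open symbols for normal B cells, filled symbols for CLL cells and a bar for the CLL mean ± SD (n = 5). Platelet markers lie below both normal samples in all 5 CLL samples, and erythroid, T cell, cytotoxic cell and monocyte markers are highest in CLL sample 4.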

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

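The tests of monocyte markers in the normal samples, of normal sample 1 for the platelet list and of a single scaling factor for CLL sample 4 were chosen after the results were seen. For the tests of normal sample 1 an SE over samples was added after, beside the SE over genes written in the predictions, because genes of a list are correlated (estimated at 0.451, 0.246 and 0.471 for the NF-kB, immediate early and interferon lists) and only normal sample 2 is left as baseline, assumed to vary like a CLL sample. All bootstrap intervals below resampled genes, not samples, so they hold no spread between samples. They also treat the genes of a list as independent, while the estimated correlation of the erythroid markers was 0.756. Of 144 measures in the 5 CLL samples, 11 had a sample that stood apart from the other 4 by more than the 5% limit of Dixon's test, where chance flags about 1 in 20 groups, or 7.2 here. CLL sample 4 accounted for 4 of the 11.

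In CLL sample 4 the log2 intensity of ADA was 13.39, against 11.73 in the next highest CLL sample, and that of GZMB was 12.78, against 9.64. The mean log2 intensity of T cell markers there was 12.84, against 11.35, and that of natural killer and cytotoxic cell markers 12.73, against 10.68. CLL sample 1 had the lowest CD74 at 15.59, with the next at 17.08, and the lowest mean of MHC class II presentation genes at 13.49, with the next at 14.43. CLL sample 2 had the lowest AXIN1 at 10.96 and the highest mean of proteasome genes at 13.62, with the next at 13.29. CLL sample 3 had the lowest mean of prognostic genes at 9.25, with the next at 11.06, and the highest GAPDH 3' to 5' ratio at 2.03, with the next at 1.15. CLL sample 5 had the highest GZMK at 13.15, with the next at 11.65.

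Erythroid transcripts were far higher in CLL sample 4 than in the other CLL samples, with a median excess of 5.94 over 7 markers, and markers of monocytes (2.52), natural killer and cytotoxic cells (2.40), neutrophils (2.09) and T cells (1.84) were in excess there too. The median excess of all tested probe sets, −0.102, decides nothing about scaling since the authors' scaling largely sets it, but a single scaling factor would move all markers alike, and the erythroid median exceeded that of pan B cell markers (−0.43) by 6.37 (95% bootstrap interval 5.03 to 8.11), which argues against it. Erythroid cells or their RNA in the sample would bring further erythroid transcripts, and 13 genes of a list written before it was looked up had a median excess of 3.43 (95% bootstrap interval 3.10 to 3.98), among them SELENBP1 at 6.71 and GMPR at 4.96. These 13 were the members that passed the filter of brightness on at least 2 arrays. Genes bright only in CLL samples 4 and 5 would pass it, so the size of this excess may be overstated. HBB decides little, as it lies near the top of the range, where differences can be compressed: its log2 intensity was 17.94 in CLL sample 4, whose brightest probe set had 18.44, 17.92 in CLL sample 5, 16.67 to 17.43 in the other CLL samples and 17.10 in normal sample 1. None of the 7 markers stands in another list, and red cell material and other blood cells in CLL sample 4 may be the source, but no sort or purity is given in the sources used here and no biological explanation was tested.

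Platelet transcripts were lower in CLL cells by a mean of −3.67. Biased RNA in normal sample 1, which had the ACTB ratio of 3.16, was argued against as the whole cause, since the mean relative to normal sample 2 alone was −4.02 (−4.76 to −3.29 at 1 SE over genes, −4.89 to −3.16 over samples). Platelets or their RNA in the normal samples are a candidate source: PF4 averaged 15.24 in normal B cells and 9.55 in CLL cells. Of 11 further platelet genes 8 lay below 0, including PRKAR2B at −3.81 and CAVIN2 at −2.59, but their median was −0.297 with a 95% bootstrap interval of −1.51 to 0.134, so this could not be told apart from other causes. These further genes passed the same filter as the platelet list, which genes bright only in the normal samples would pass. A difference between leukemic and normal B cells themselves stays open, as untested.

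Immediate early, NF-kB and interferon genes were lower in CLL cells, 53 of 57 members in all, with a median of −0.77. Over genes, the values argued against biased RNA in normal sample 1 as the whole cause. Relative to normal sample 2 alone the mean over the members was −0.992 (−1.13 to −0.856 at 1 SE over genes), below the bound of −0.5 set before. Over samples, with 1 normal array left, 1 SE spans −1.52 to −0.465 and so reaches that bound. RNA in CLL sample 3, with a GAPDH ratio of 2.03, was not tested this way. That sample had the lowest NF-kB (−1.92) and interferon (−1.98) means of the CLL samples, though CLL sample 2 had the lowest immediate early mean (−1.64). Without CLL sample 3 all 3 lists stayed called with the preset correlation. Over all samples, 0 of the 3 were called with an estimated correlation. Monocytes in the normal samples may contribute: the median of 13 monocyte markers was −0.88, and it differed from that of the members by −0.113 with a 95% bootstrap interval of −0.883 to 1.17, which is too wide to decide, and the markers went both ways. By sample, CLL samples 4 and 2 had the highest interferon means (0.08 and −0.30) and monocyte means (1.47 and −0.31) of the CLL samples. The NF-kB mean was highest in CLL samples 4 and 5, and the immediate early mean in CLL sample 1. Of the members, 14 of 14 NF-kB targets, 19 of 21 immediate early genes and 18 of 22 interferon genes were brighter than the typical array median in CLL cells too. A difference between leukemic and normal B cells, or in how the cells were handled before lysis, stays open, as untested.

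The 7 samples can be split into 2 and 5 in 21 ways, and chance could not be excluded for any of the counts set against these splits. As many gene lists as the real 7 were called in 2 of 21 splits, the real one included, with 9 as the highest of the others, and as many cell type lists as the real 6 in 3 of 21, with 7 as the highest. As many probe sets at an unadjusted p under 0.05 as the real 828 came from 4 of 21, with 1575 as the highest, when CLL samples 1 and 2 were set against the rest.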

How the results depend on the processing

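The fit without CLL samples 3 and 4 was the only setting here chosen after the data were seen. Of 1783 results for named genes under other settings, 1758 kept their side of the threshold, 25 passed it where they had not before, and 8 changed sign. Since no named gene passed in the main fit, keeping its side means staying uncalled. That says little about how stable the differences are. Of 644 results for lists, 594 kept their side, 33 lost and 17 gained a call. In 43 the camera direction changed, all among results that were not called. That direction can differ from the sign of the list mean, so these are not all reversed means. With 5 against 2 arrays, simulated changes of 2-fold were called in 2.8% of probe sets, which limits what a count of 0 shows.

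Probe sets called higher and lower, 0 and 0 in the report, numbered 2 and 6 with a pseudocount of 263.2, 1 and 7 without the intensity trend, and 14 and 20 with array weights. Leaving out each sample in turn gave 0 to 2 higher and 0 lower, with 2 without normal sample 1 and 1 without CLL sample 1. They stayed at 0 and 0 with quantile normalization, median centring, either other filter, robust estimation, 1 value per gene, a 2-fold minimum, and CLL samples 3 and 4 left out. Gene lists called numbered 7 to 10 and cell type lists 2 to 7 when each sample was left out in turn, the 2 without normal sample 2. With an estimated correlation they numbered 0 and 1. Without CLL samples 3 and 4 they numbered 9 and 4, and the T cell and plasma cell calls were lost (adjusted p = 0.131 and 0.0649). A stricter filter also ended the T cell call (0.0827). Without a filter the median correlation between CLL samples was 0.857, and that between normal and CLL samples 0.874. The NF-kB, immediate early, interferon, glycolysis and platelet lists were called under all 17 settings with the preset correlation, with largest adjusted p of 0.000223, 0.000729, 0.00201, 0.00884 and 1.16e-07. The cause of these shifts was not tested, except that fewer arrays or genes enter some fits.

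Replicate numbers 1 and 2 occur in both groups, but the labels do not say that they pair samples, and deviations of same-numbered samples correlated at only 0.0280 for number 1. The replicate number was still tried as a block (replicate block). Numbers 3, 4 and 5 occur only among CLL samples, so those samples did not inform the difference. That fit therefore compared only CLL samples 1 and 2 with the 2 normal samples, and these alone informed its residual error. It called 12 probe sets higher and 29 lower, and 5 gene lists and 3 cell type lists. Calls not made with the block were those of genes known to be high in CLL (adjusted p = 0.180), ribosomal (0.103), proteasome (0.205), T cell (0.495), plasma cell (0.448) and erythroid (0.279) genes, and 1 was gained, that of MHC class II presentation (mean −0.62, adjusted p = 0.0366).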

Other observations

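The test of immunoglobulin probe sets was chosen after the result was seen. Immunoglobulin transcripts, which B cells make to build their receptor and plasma cells to secrete antibody, were lower in CLL cells as a group. Of 32 tested probe sets with an immunoglobulin symbol, 31 lay below 0, 11 of them at an unadjusted p under 0.05, and the median difference was −1.85 on the log2 scale. Many of these probe sets (22 of 32) are of a kind that can detect several related transcripts, so they are not separate measurements. Their mean difference was −1.99, and 2 of the 21 splits of the samples gave a mean as large in size, the real one included, with 2.12 as the highest of the others, so chance could not be excluded. Plasma cell markers, with a mean of −1.15, were lower in the same comparison.

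CLL sample 1 had the lowest mean of the CLL samples for 5 B cell gene groups, picked after the values were seen. Its means relative to normal B cells were −0.27 for genes known to be high in CLL, −1.19 for MHC class II presentation and −1.28 for naive B cell genes, while the other 4 samples lay between 0.84 and 2.28, between −0.25 and −0.01, and between −0.33 and 0.61. They were −0.25 for B cell receptor signalling and −0.55 for B cell differentiation factors, with the other 4 between −0.04 and 0.36 and between −0.26 and 0.14. Only the MHC class II mean passed the 5% limit of Dixon's test. For pan B cell markers and surface genes known to be dim in CLL, the lowest means were those of CLL sample 4, at −0.88 and −0.83. ROR1, CD5 and BCL2 were brighter in CLL sample 1 than in both normal samples.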
